A study of Homo sapiens with 9 samples.

How the data were processed

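Total RNA of the MCF7, CCD18 and Ramos cell lines, grown under standard conditions without treatment, was extracted with TRIzol and purified on columns. Per the labels, it was converted to sense-strand cDNA with a whole-transcript kit, fragmented, labelled with biotin and hybridized to an Affymetrix gene array. There were 3 lines with 3 arrays each, 9 arrays in all, and the labels number the replicates of each line without saying whether they came from separate cultures. The deposited values are log2 probe set intensities made by the authors with RMA (robust multi-array average: background correction, quantile normalization and median polish), per the submitters' processing notes, which give no version or settings. The table holds 28244 probe sets with no missing values, and all of its columns were used. The values' distributions were checked on the table: they match within each line and differ between lines, so that the normalization appears to have been run for each line on its own. Differences between lines therefore hold any difference in overall intensity between the 3 sets of arrays. Precision is limited by the number of arrays, and by replicate values that are often identical.

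Probe sets were paired with genes through the platform annotation. Of the probe sets, 19158 had 1 gene symbol, 1388 had several and 7698 had none. In all, 19128 of the single-gene probe sets were matched to a gene table of assembly GRCh38.p14, from which current symbols, biotypes and the order of genes along chromosomes were taken. Probe sets of Y-linked genes, XIST and TSIX (68) were left out of every table. For each gene the probe set with the highest mean over the 9 arrays was kept, which left 18381 genes, 16884 of them protein coding. Of 636 genes with several probe sets, 121, 106 and 142 had called probe sets of both directions in the comparisons of MCF7 with CCD18, MCF7 with Ramos and CCD18 with Ramos.

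Genes were compared with limma 3.58.1 in R 4.3.3: one linear model of the 9 arrays with the cell line as the only factor, moderated by eBayes (6 residual degrees of freedom, 0.329 prior degrees of freedom), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Folds are differences between mean log2 values, taken back to the linear scale. A gene set one line apart when it was higher by 2-fold or more, at an adjusted p under 0.05, than in each of the other lines. Because the 3 arrays of a line often hold identical values, the residual variance of 5962 genes was 0 and was offset by limma. The p-values therefore serve to rank and to set a threshold, not as a measure of how cultures vary. The median SE of a log2 difference was 0.00893.

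There were 32 gene lists of cell types, pathways and complexes with 771 members in all, of which 687 were measured. Each list was tested in each comparison with camera from limma, with its preset correlation of 0.01 between genes, adjusted over the 96 tests. Camera asks whether the genes of a list differ more toward one line than all other genes do, so a list can be placed toward a line while its own median difference is near 0 or of the other sign. Camera with an estimated correlation (statmod 1.5.0) and fry were run beside it. With an estimated correlation, calls were also lost for lists whose estimate lay below 0.01. For MCF7 versus CCD18, for example, the estimate was -0.00026 for the luminal list and -0.038 for the housekeeping list. A call lost in this way therefore need not come from correlation between genes. The median difference of each list was set against those of 1000 random lists, drawn with as many genes from each of 20 bins of the mean over the 9 arrays. The arrays' detection limits were not used here, and the median of the olfactory receptor genes of each line served as a rough background level. Whether the genes that set a line apart held more members of a list than chance gives was tested with a one-sided Fisher's exact test against all genes tested, adjusted over 96 tests, a test that was chosen after seeing the data.

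The groups, the comparisons, the tests, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. By that rule the text names, per comparison, the 8 genes with the largest fold in each direction among those with an adjusted p under 0.05 and no overlap between the arrays of the lines. It also names the 8 genes that set each line furthest apart, and for each list it describes 2 to 4 members with the largest folds and members that went the other way. Pseudogenes, probe sets with several symbols and unnamed loci were left out. Departing from the rule, list members that did not pass and, in comparisons with CCD18, members under 2-fold that went the other way are given as counts. In places the list members named are also not those with the largest folds, and some that went the other way are left unnamed.

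Among the alternative settings were 3 of scaling: centring each array on its median, quantile normalization over the 9 arrays, and centring on the housekeeping list. The others were filters on low values (14680 genes above the median and 17119 above the 25th percentile in at least 1 line), all 28176 probe sets kept, the mean of a gene's probe sets, eBayes with a trend and a robust prior, array weights, the replicate number as a block, each array left out in turn, fits of 6 arrays only, and limma treat against a fold of 1.5. Another 4 were chosen after seeing the data: arrays set to one median and one median absolute deviation, a floor on the spread, a fit without the 3 CCD18 arrays, and camera with an estimated correlation after quantile normalization. The procedure was tested on simulated data with known differences. At a log2 difference of 0.5 it recovered 94% and 92% of 50 changed genes in the comparisons of MCF7 with CCD18 and with Ramos, and 100% at 1, 2 and 3. There were 14 and 16 calls among 18181 unchanged genes and 0 among 18381 in the third comparison. The noise was drawn with each gene's own replicate variance, which was 0 for 5962 genes. For those genes a difference could hardly be missed and a false call could hardly arise. The simulation therefore does not show how often calls would be false if separate cultures vary more than these arrays. In the same test camera found a shifted list and also called 2 others of the 32 lists. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.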

Results

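Gene expression was measured in 3 untreated human cell lines with 3 arrays each. MCF7 is an epithelial line from a breast cancer, CCD18 a fibroblast line from the colon and Ramos a B lymphocyte line from a Burkitt's lymphoma. The deposited values are RMA log2 intensities, and 18381 genes were compared, of which 16884 are protein coding. Protein-coding genes had a median log2 value of 8.10 on the MCF7 arrays, 6.48 on the CCD18 arrays and 7.50 on the Ramos arrays. Their spread over genes was also narrower in CCD18, with an SD of 1.30 against 2.13 in MCF7 and 2.12 in Ramos. The 24 measured genes of a housekeeping list, which serve functions that all cells need, had a median of 11.8 in MCF7, 7.45 in CCD18 and 11.2 in Ramos. Of 8 probe sets for ribosomal RNA, 7SK and 7SL, 6 lay at 13.45 to 14.4 in all 3 lines, close to the highest value of each array (14.4 to 14.81), where saturation can hide a difference. The other 2 are of the 7SL pseudogenes RN7SL832P and RN7SL737P. They lay at 6.42 and 7.03 in CCD18, against 7.84 and 8.23 in MCF7 and 6.21 and 8.33 in Ramos. The median of 337 olfactory receptor genes, which these cell types are not known to use, was 5.05 in MCF7, 5.38 in CCD18 and 4.89 in Ramos. Of the 337, 217 were higher in CCD18 than in both other lines and 45 were lower than in both. Across probe sets, arrays of MCF7 and Ramos correlated with Pearson's r of 0.859 to 0.860, and CCD18 arrays with r of 0.603 to 0.608 against MCF7 and 0.583 to 0.585 against Ramos. These correlations run over probe sets within pairs of arrays, and probe sets are not independent replicates.

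**Figure D1:**
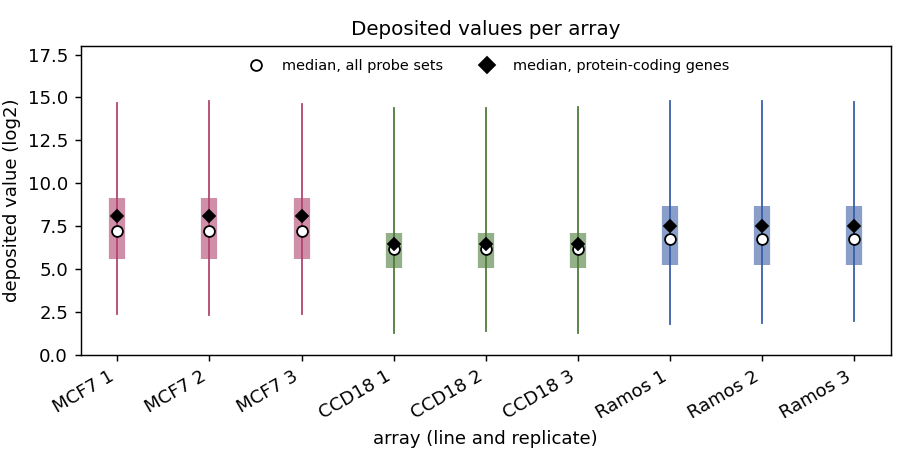
Deposited log2 values of all 28244 probe sets on each of the 9 arrays (thin lines, whole range, thick bars, quartiles, circles, medians, diamonds, medians of the protein-coding genes). The protein-coding median was 8.10 on the MCF7, 6.48 on the CCD18 and 7.50 on the Ramos arrays, with nearly one distribution within each line.

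The distributions were matched within each line and not over the 9 arrays. Sorted values of the 3 arrays of a line differed by at most 0.047 between the 1st and 99th percentiles, while those of MCF7 and CCD18 differed by up to 3.08. Between CCD18 and Ramos the largest gap was 2.75, and between MCF7 and Ramos 0.517. The median difference over all genes was 1.08 for MCF7 minus CCD18, 0.35 for MCF7 minus Ramos and -0.38 for CCD18 minus Ramos. After quantile normalization over the 9 arrays it was -0.46, -0.07 and 0.54. Counts of genes per direction therefore depend on the scaling. Counts are as deposited unless a rescaling is named, and those over all genes and of the called lists are also given after quantile normalization. Centring on array medians or on the housekeeping list shifts all genes of a comparison by one amount, so a direction that turns under it reflects only the size of the difference as deposited. Folds are as deposited. Where the lower line lies at or below its olfactory receptor median, it cannot be told from background, and the size and rank of the fold are uncertain. Replicate arrays often held one value: the 3 arrays were identical for 60.8% of genes in MCF7, 72.2% in CCD18 and 63.0% in Ramos, and 5962 genes (32.4%) had no spread in any line. Standard errors from these replicates are therefore very small, and the labels do not say whether the replicates were separate cultures. With 3 arrays against 3, a 2-sided exact permutation test of a single gene cannot go below p = 0.1.

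Epithelial genes were much higher in MCF7 than in Ramos. E-cadherin (CDH1), the adhesion protein of epithelial junctions, had a log2 value of 13.25 ± 0 in MCF7 and 5.56 ± 0 in Ramos (SD, n = 3 arrays each) and was 207-fold higher. The epithelial surface protein EPCAM was 136-fold higher, and the keratins KRT8 and KRT19, which form the filaments of simple epithelia, were 132-fold and 113-fold higher. Of the 27 measured genes of the epithelial junction and keratin list, 26 were higher in MCF7, 25 of them by 2-fold or more. The exception was ST14, a membrane serine protease, which was 3.3-fold higher in Ramos, and KRT7 was only 1.92-fold higher in MCF7. All 19 measured genes of the luminal breast and estrogen receptor list were higher in MCF7, 18 by 2-fold or more. They included the secreted disulfide isomerase AGR2 at 137-fold, the luminal transcription factors GATA3 at 101-fold and TFAP2C at 84.8-fold, and the estrogen receptor ESR1 at 60.6-fold. A second probe set of ESR1 differed less, by 1.63 on the log2 scale against 5.92 for the one used. XBP1, a factor of secretory cells including plasma cells, was 1.67-fold higher. Camera, a limma test that compares the genes of a list with all other genes, placed both lists toward MCF7, with an adjusted p = 0.0025 for the epithelial list and 0.0046 for the luminal list. Both calls held with an estimated correlation, at adjusted p = 0.0424 and 0.0497. With an estimated correlation after quantile normalization they were lost, at adjusted p = 0.28 and 0.25, and no list was called in any of the 3 comparisons, the smallest adjusted p being 0.18. After quantile normalization 25 epithelial and 17 luminal genes were 2-fold or more higher in MCF7.

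B cell and leukocyte genes were much higher in Ramos. CD20 (MS4A1), a surface protein of B cells, had a log2 value of 12.33 ± 0.013 in Ramos and 4.65 ± 0.054 in MCF7 (SD, n = 3 arrays each) and was 206-fold higher in Ramos. Of the 22 measured B cell identity genes, 21 were 2-fold or more higher in Ramos, among them TCL1A at 251-fold, the B cell receptor component CD79A at 89.3-fold and the lineage factor PAX5 at 11.6-fold. CD24, a surface protein that epithelial cells also carry, went the other way and was 20.8-fold higher in MCF7. In the germinal centre list, 17 of 18 genes were higher in Ramos, 14 by 2-fold or more, and 1 did not pass. Examples were RGS13 at 171-fold, STAP1 at 114-fold, CD38 at 95.7-fold and BCL6, the repressor that directs germinal centre B cells, at 17.6-fold. Among the pan-leukocyte genes, 17 of 19 were higher in Ramos, with LAPTM5 at 125-fold, CD45 (PTPRC) at 100-fold and ARHGDIB at 93.3-fold. The other 2, the phosphatase PTPN6 and the zinc finger factor IKZF2, were 2.1-fold and 1.77-fold higher in MCF7. Plasma cell genes were split: 9 of 11 were higher in Ramos, among them the immunoglobulin joining chain JCHAIN at 516-fold, IRF4 at 81.6-fold and CD27 at 33.1-fold. JCHAIN had a log2 value of 4.55 in MCF7, below the olfactory receptor median, and against that median it was 364-fold higher in Ramos. The plasma cell surface proteoglycan SDC1, which epithelia also make, was 7.55-fold and SSR4 1.78-fold higher in MCF7. The camera adjusted p was 1e-10 for the B cell, 5.4e-09 for the germinal centre, 3.2e-07 for the pan-leukocyte and 0.0016 for the plasma cell list. With an estimated correlation it was 0.0424, 0.038, 0.038 and 0.0424. After quantile normalization over the 9 arrays the plasma cell call was lost, at adjusted p = 0.083, and 21 B cell, 15 germinal centre, 15 pan-leukocyte and 8 plasma cell genes were 2-fold or more higher in Ramos.

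**Figure D2:**
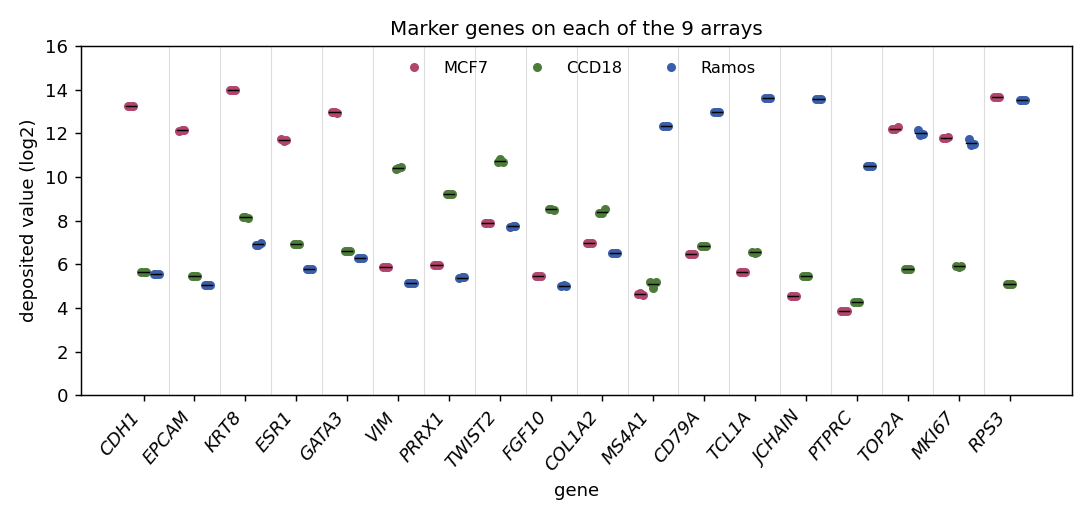
Deposited log2 value of marker genes on each of the 9 arrays (points, 3 per line, black bars, means). CDH1 stood at 13.25 in MCF7 and 5.56 in Ramos, MS4A1 at 12.33 in Ramos and 4.65 in MCF7, and VIM at 10.42 in CCD18.

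Antigen presentation and interferon response genes were mostly higher in Ramos. All 10 measured genes of the MHC class I presentation list were 2-fold or more higher there, including the immunoproteasome subunit PSMB9 at 13.2-fold, beta-2 microglobulin (B2M) at 6.76-fold and the peptide transporter TAP1 at 4.5-fold. In the MHC class II list, 10 of 11 genes were higher in Ramos, with HLA-DPA1 at 170-fold and the class II transactivator CIITA at 2.62-fold, while HLA-DQB1 had a log2 value of 5.42 in MCF7 and 3.75, below the olfactory receptor median, in Ramos, so that its direction is uncertain. HLA genes are polymorphic and alike in sequence, and their single values are less certain than those of other genes. Interferon response genes went both ways: 15 of 27 were higher in Ramos, 10 were higher in MCF7 and 2 did not pass. The antiviral genes OAS2 and MX1 were 20.8-fold and 6.54-fold higher in Ramos, and IFITM3 and IFITM2 were 31.7-fold and 7.85-fold higher in MCF7. Among cytosolic ribosomal protein genes, 21 of 38 were higher in Ramos, 11 were higher in MCF7 and 6 did not pass. Only RPL10 at 4.82-fold and RPS23 at 2.61-fold, both toward Ramos, were 2-fold or more apart. Camera gave an adjusted p of 2.8e-06 for class I, 0.00012 for class II, 0.0011 for interferon and 0.0012 for ribosomal protein genes, all toward Ramos. With an estimated correlation these were 0.0424, 0.0726, 0.0424 and 0.0497, so the class II call was lost. The ribosomal protein call was lost after quantile normalization, at adjusted p = 0.062. After quantile normalization 10 class I, 10 class II, 11 interferon and 4 ribosomal protein genes were 2-fold or more higher in Ramos. Apoptosis regulators were called toward Ramos at adjusted p = 0.041, with adjusted p = 0.096 with an estimated correlation and 0.56 after quantile normalization. Of their 26 genes 13 were higher in Ramos, 12 were higher in MCF7 and 1 did not pass. By 2-fold or more 6 were higher in Ramos and 3 in MCF7, or 9 and 0 after quantile normalization. PMAIP1, the death receptor FAS and HRK were 8.92-fold, 4.99-fold and 4.86-fold higher in Ramos, and CASP6 and the survival factor BCL2 3.3-fold and 2.25-fold higher in MCF7.

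**Figure D3:**
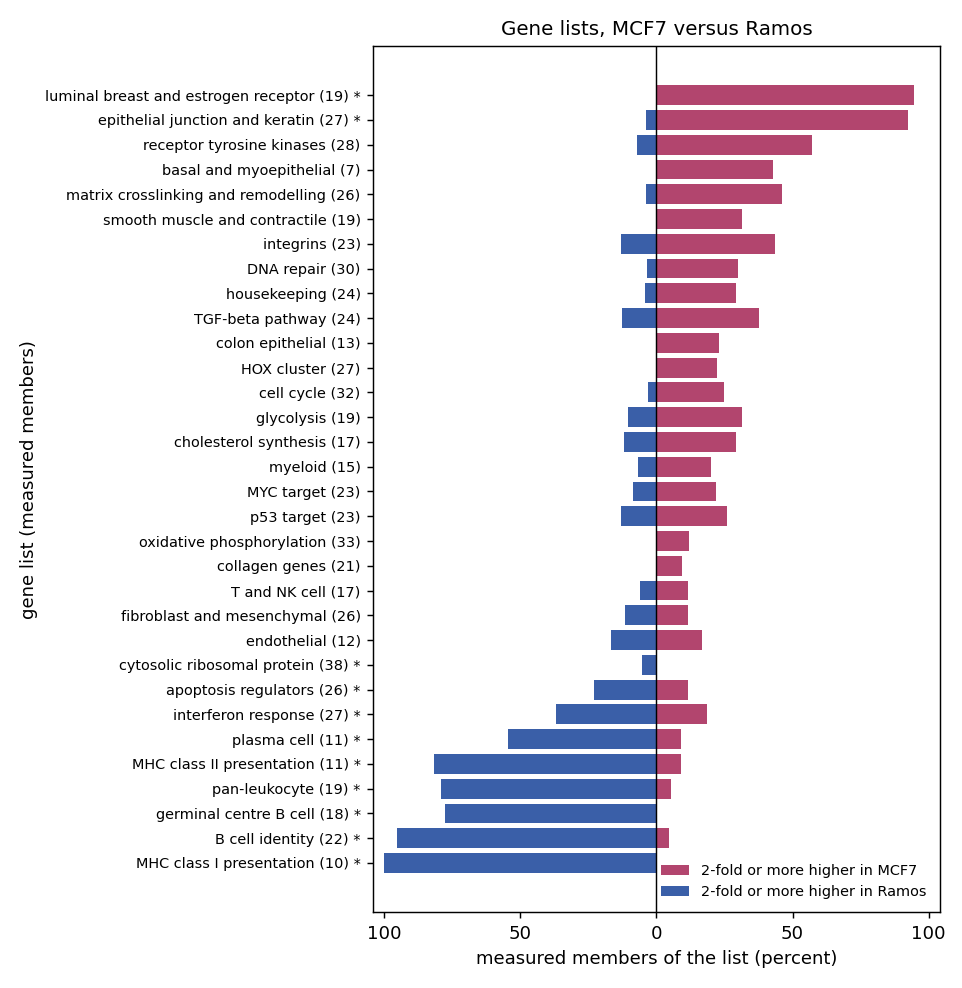
Percent of the measured members of each of the 32 gene lists that were 2-fold or more higher in MCF7 (right) or in Ramos (left) at an adjusted p under 0.05, with stars at the 11 lists called by camera. The epithelial list reached 25 of 27 toward MCF7 and the B cell list 21 of 22 toward Ramos.

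Across all genes, 17622 of 18381 differed between MCF7 and Ramos at a limma adjusted p under 0.05, 12842 higher in MCF7 and 4780 higher in Ramos. By 2-fold or more, 3996 were higher in MCF7 and 1362 in Ramos. Rescaling moved this balance: 2127 and 1809 after quantile normalization, 2172 and 2656 after centring on array medians, and 2110 and 2768 after centring on the housekeeping list. The largest folds toward MCF7 were those of SPTSSB, a subunit of the first enzyme of sphingolipid synthesis, at 402-fold, RHOBTB3 at 394-fold, the neuropeptide Y receptor NPY1R at 357-fold and the Wnt inhibitor DKK1 at 352-fold. PLOD2, a collagen lysyl hydroxylase, MAL2, the fatty acid elongase ELOVL2 and NRIP1, a corepressor of nuclear receptors, followed at 277-fold, 273-fold, 270-fold and 267-fold. Toward Ramos, JCHAIN was followed by the DNA sensor IFI16 at 306-fold, the lactate dehydrogenase subunit LDHB at 276-fold, TCL1A at 251-fold, IRAG2 at 222-fold, the sialyltransferase ST6GAL1 at 218-fold and the B cell exchange factor RASGRP3 at 209-fold. Arrays of the lines did not overlap for 97.3% of genes. Where replicate values are often identical, a small offset between lines is enough for this. The 10% that chance gives for exchangeable arrays is therefore no yardstick here. Of 101 genes examined singly in this comparison, not all of which are named here, 25 lay at or below the olfactory receptor median in the lower line. They included all of the genes with the largest folds just listed but MAL2, TCL1A and ST6GAL1. Against that median the fold was 99.6 for NPY1R, 88.6 for PLOD2 and 132 for IFI16. For the 101 genes, all of which passed without overlap, the median SE of the log2 difference was 0.012 and the largest 0.15, and 27 had no spread in either line. Of 687 list memberships, 655 passed with p adjusted over all genes and 655 with p adjusted over the list alone.

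The comparison of MCF7 with CCD18 was dominated by a general difference in level. By 2-fold or more 9407 genes were higher in MCF7 and 303 higher in CCD18 as deposited, 5140 and 6701 after quantile normalization, 5826 and 7576 after centring on array medians, and 803 and 14543 after centring on the housekeeping list. A total of 17871 genes differed at a limma adjusted p under 0.05, 12806 higher in MCF7 and 5065 in CCD18, and the arrays of the lines did not overlap for 98.1% of genes. Genes 2-fold or more higher in CCD18 included 7 of the 26 genes of the fibroblast and mesenchymal list. Vimentin (VIM), the intermediate filament of mesenchymal cells, had a log2 value of 10.42 ± 0.044 in CCD18 and 5.86 ± 0 in MCF7 (SD, n = 3 arrays each) and was 23.7-fold higher in CCD18. The mesenchymal transcription factors PRRX1, TWIST2 and TWIST1 were 9.63-fold, 7.11-fold and 2.1-fold higher, N-cadherin (CDH2) was 3.18-fold higher, and TCF4 and ZEB2 were 14.8-fold and 6.24-fold higher. A second probe set of ZEB2 differed by only 0.12 in the opposite direction. Of the 26 genes of that list 17 were higher in CCD18 and 9 were higher in MCF7. Of the 9, fibronectin (FN1) at 5.75-fold and the ectonucleotidase NT5E at 4.79-fold passed 2-fold, although both were lower in MCF7 after centring on the housekeeping list. Of 21 collagen genes 15 were higher in CCD18, as deposited only COL1A2 by 2-fold or more, at 2.71-fold. After quantile normalization 17 of the collagen genes, and 19 after centring on array medians, were 2-fold or more higher in CCD18, as were 16 and 19 of the fibroblast genes. COL12A1 was 3.8-fold higher in MCF7, or lower after centring on the housekeeping list.

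Camera placed the fibroblast list toward CCD18 at adjusted p = 0.00083 and the collagen list at 0.001, each 0.0424 with an estimated correlation. Lists of cell types that neither line belongs to moved the same way in camera: T and NK cell at adjusted p = 6.1e-05, myeloid at 0.0025, B cell identity at 0.0025, colon epithelial at 0.011 and endothelial at 0.011, and the HOX genes at 0.0025. With an estimated correlation the adjusted p was 0.0424 for T and NK cell, 0.0437 for myeloid and 0.0424 for HOX genes, but 0.133 for B cell identity and 0.0701 for colon epithelial and endothelial genes, so those 3 calls were lost. As deposited the median difference among 17 T and NK cell genes was -0.37, and after quantile normalization it was -1.84, with 14 of the 17 genes 2-fold or more higher in CCD18. So were then 11 of 15 myeloid, 15 of 22 B cell, 9 of 13 colon epithelial, 7 of 12 endothelial and 20 of 27 HOX genes. As deposited 0 genes of each of these lists were 2-fold or more higher in CCD18. In MCF7 1, 1, 2, 1 and 4 were, in that order. The only T and NK cell gene 2-fold or more apart as deposited was GATA3, a T cell and luminal breast factor, at 81.8-fold higher in MCF7. For the T and NK, B cell, colon, endothelial and HOX lists the mean difference was above 0, at 0.02, 0.24, 0.37, 0.09 and 0.11, although the median and the test pointed to CCD18. Large members toward MCF7 were CD24 at 411-fold in the B cell list and the carbonic anhydrase CA2 at 58.3-fold in the colon list. Within each array, by contrast, the median collagen gene ranked at percentile 83.6 in CCD18 against 38.2 in MCF7 and 37.1 in Ramos, and the median fibroblast gene at 62.6 against 21.6 and 23.8. The median T and NK cell gene also ranked higher in CCD18, at 57.5 against 28.6 and 33.6. Olfactory receptor genes lay toward CCD18 too, with a median MCF7 minus CCD18 difference of -0.26 as deposited. The medians of the collagen (-0.16), myeloid (-0.18), colon epithelial (-0.18), HOX (-0.2) and B cell (-0.22) lists were no further toward CCD18. Those of the fibroblast (-0.54), T and NK cell (-0.37) and endothelial (-0.32) lists were further.

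Toward MCF7, epithelial and growth-related lists were called. All 27 epithelial genes were higher in MCF7, 26 by 2-fold or more, with CDH1 at 192-fold, EPCAM at 102-fold, KRT18 at 57.1-fold and KRT8 at 56.4-fold. MARVELD2 was 76.3-fold higher as measured, from a log2 value of 3.73 in CCD18, below the olfactory receptor median of 5.38. The camera adjusted p of the epithelial list was 0.0025, or 0.0424 with an estimated correlation. All 19 luminal genes were 2-fold or more higher, with AGR2 at 141-fold, the zinc transporter SLC39A6 at 102-fold and GATA3 at 81.8-fold. Their adjusted p was 0.0086, or adjusted p = 0.0622 with an estimated correlation. All 32 cell cycle genes were 2-fold or more higher, including the mitotic kinase AURKA at 121-fold, TOP2A at 87.1-fold, CCNB2 at 72.4-fold and MKI67 at 58.4-fold. Their adjusted p was 0.048, or adjusted p = 0.703 with an estimated correlation. Ribosomal protein genes (36 of 38 by 2-fold or more, RPS3 at 386-fold, RPS13 at 372-fold), oxidative phosphorylation genes (32 of 33, NDUFB5 at 141-fold) and DNA repair genes (30 of 30) were called too. Ribosomal protein genes have many like copies in the genome, and their single values are less certain: a second probe set of RPL14 differed by 1.12 on the log2 scale, against 8.32 for the one used. The adjusted p of these 3 lists was 0.0045, 0.0052 and 0.0084, and adjusted p = 0.0743, 0.212 and 0.2 with an estimated correlation. The p53 target (20 of 23, CCNG1 at 248-fold and MDM2 at 176-fold), MYC target (23 of 23), cholesterol synthesis (16 of 17), apoptosis (17 of 26) and housekeeping (24 of 24) lists followed. They had adjusted p = 0.029, 0.02, 0.021, 0.043 and 0.036, and adjusted p = 0.087, 0.0746, 0.18, 0.096 and 0.0939 with an estimated correlation. After quantile normalization 18 epithelial, 16 luminal, 24 cell cycle, 24 ribosomal protein, 24 oxidative phosphorylation and 23 DNA repair genes were 2-fold or more higher in MCF7. So were 13 p53 target, 14 MYC target, 13 cholesterol synthesis, 12 apoptosis and 15 housekeeping genes. Each list was also set against 1000 random lists of genes with like mean values. Of the 19 called lists 8 had a median between the 2.5th and 97.5th percentiles of these lists, namely the colon epithelial, myeloid, endothelial, p53 target, apoptosis, cholesterol, MYC target and housekeeping lists. The housekeeping median, for one, was 4.22 against 3.45. Of the 19 calls in this comparison, 13 were lost with an estimated correlation, and the colon epithelial and apoptosis calls were lost after quantile normalization, at camera adjusted p = 0.1 and 0.081.

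The largest differences toward MCF7 as measured were those of MPLKIP at 734-fold, the DNA helicase BRIP1 at 571-fold, CMC2 at 492-fold, the kinetochore protein SKA2 at 446-fold, CD24 and the glutathione transferase MGST1 at 411-fold each, RPS3 and RPS13. All 8 lay below the olfactory receptor median of 5.38 in CCD18, as at 3.94 for MPLKIP, 3.65 for BRIP1 and 4.03 for CMC2. Against that median they were 271-fold, 171-fold and 192-fold higher and RPS3 was 312-fold higher, so that their order is uncertain. Of 56 genes examined singly in this comparison, not all of which are named here, 25 lay at or below the olfactory receptor median of the lower line. MPLKIP has 3 probe sets, and the other 2 differed by 7.59 and 1.89 on the log2 scale against 9.52 for the one used. Toward CCD18, VIM and TCF4 were followed by complement C2 at 14.1-fold, PRRX1, the repressor ZBTB18 at 8.8-fold, the fibroblast growth factor FGF10 at 8.25-fold, ZBTB20 at 8.14-fold and AGPS, an enzyme of ether lipid synthesis, at 7.53-fold, or 2.78-fold against the olfactory receptor median of MCF7. A second probe set of C2 differed by -0.03 only, and C2 had the largest SE of the named genes, 0.74. All 56 genes examined singly in this comparison passed, with a largest adjusted p of 0.0019 by limma and a median SE of 0.018. Of them 12 had no spread in either line. Of 687 list memberships, 677 passed with p adjusted over all genes and 676 with p adjusted over the list alone.

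Between CCD18 and Ramos, most mesenchymal and matrix genes were higher in CCD18 and most B cell and pan-leukocyte genes in Ramos. VIM was 39.4-fold higher in CCD18, PRRX1 14.4-fold, FGF10 11.3-fold, TWIST2 8.01-fold, SNAI2 4.54-fold and CDH2 3.24-fold. Of the 26 fibroblast and mesenchymal genes, 20 were higher in CCD18, 8 of them by 2-fold or more, 5 were higher in Ramos and 1 did not pass. The 5 included ZEB1, a repressor that lymphocytes also use, at 16.5-fold, and TCF4, a factor of B cells as well, at 6.85-fold, but TCF4 was higher in CCD18 after quantile normalization. Of 21 collagen genes 19 were higher in CCD18, 4 by 2-fold or more: COL1A2 at 3.66-fold, COL3A1 at 2.2-fold, COL5A1 at 2.06-fold and COL6A3 at 2.05-fold. The median CCD18 minus Ramos difference was 0.58 for collagen and 0.54 for fibroblast genes, and also 0.58 for colon epithelial and 0.68 for myeloid genes. Olfactory receptor genes lay toward CCD18 as well, at a median Ramos minus CCD18 of -0.41, so small differences toward CCD18 do not by themselves show use of a gene. Matrix crosslinking and remodelling genes were higher in CCD18 for 21 of 26, with the metalloproteinase inhibitor TIMP2 at 5.02-fold. PLOD2 was 5.79-fold higher in CCD18 as measured, but only 1.85-fold against the olfactory receptor median, below which it lay in Ramos. In Ramos 3 were 2-fold or more higher, one being the lysyl oxidase LOXL2 at 9.58-fold, which was higher in CCD18 after centring on the housekeeping list. Camera gave an adjusted p of 0.0015, 0.00012 and 0.0011 for the fibroblast, collagen and matrix lists, and 0.0424 for each with an estimated correlation. The epithelial list was also called toward CCD18, at adjusted p = 0.0015 and 0.0424 with an estimated correlation. Of its 27 genes 22 were higher in CCD18 but only 3 by 2-fold or more, and 3 were 2-fold or more higher in Ramos, such as ST14 at 32.6-fold. Lists of cell types in neither line were called toward CCD18 as well, the colon epithelial genes at adjusted p = 0.0023, the myeloid genes at 0.0025 and the T and NK cell genes at 0.009, the last with adjusted p = 0.0643 with an estimated correlation. The HOX genes (24 of 27 higher in CCD18) and receptor tyrosine kinases (22 of 28, PDGFRA at 2.57-fold) were called at adjusted p = 0.00071 and 0.0014, each 0.0424 with an estimated correlation. The integrin (17 of 23), basal (6 of 7) and smooth muscle (13 of 19, the actin crosslinker ACTN1 at 3.72-fold) lists had adjusted p = 0.0065, 0.014 and 0.031, and adjusted p = 0.0523, 0.0799 and 0.15 with an estimated correlation. By 2-fold or more 4 integrin and 4 smooth muscle genes were higher in CCD18, against 4 and 3 in Ramos. The mean of the integrin genes was -0.03 where their median was 0.53. After quantile normalization 18 fibroblast, 17 collagen, 19 matrix, 18 epithelial, 11 colon epithelial, 10 myeloid, 12 T and NK cell, 20 HOX, 18 receptor tyrosine kinase, 13 integrin, 4 basal and 12 smooth muscle genes were 2-fold or more higher in CCD18. As deposited this count was 6 for matrix, 2 for colon epithelial, 2 for myeloid and 1 for T and NK cell genes. It was 3 for HOX, 5 for receptor tyrosine kinase and 0 for basal genes.

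In Ramos, 21 of 22 B cell identity genes were 2-fold or more higher than in CCD18, with MS4A1 at 149-fold, TCL1A at 136-fold and the inhibitory receptor CD22 at 98.6-fold. Germinal centre genes were 2-fold or more higher for 16 of 18, with the peptidase CD10 (MME) at 146-fold and RGS13 at 122-fold. Pan-leukocyte genes were so for 16 of 19, with ARHGDIB at 207-fold and the actin bundling protein LCP1 at 142-fold. All 10 MHC class I genes were 2-fold or more higher in Ramos, B2M by 173-fold from a log2 value of 4.74 in CCD18, or by 111-fold against the olfactory receptor median of 5.38. The camera adjusted p was 7e-04 for the B cell list, 0.0025 for the germinal centre and pan-leukocyte lists and 0.0098 for the class I list. With an estimated correlation it was 0.0935, 0.0437, 0.0424 and 0.0701, so the B cell and class I calls were lost. The growth and housekeeping lists that were called toward MCF7 against CCD18 were called toward Ramos too. All 32 cell cycle genes were 2-fold or more higher in Ramos, with TOP2A at 75.3-fold and CCNB2 at 62.9-fold. So were 36 of 38 ribosomal protein genes, 32 of 33 oxidative phosphorylation genes, 27 of 30 DNA repair genes, 19 of 23 MYC target genes, 24 of 24 housekeeping genes and 16 of 17 cholesterol synthesis genes, the sterol oxidase MSMO1 by 369-fold. Their adjusted p was 0.0025, 0.00034, 0.00034, 7e-04, 0.0025, 0.0025 and 0.0025 in that order. With an estimated correlation it was 0.549, 0.0424, 0.116, 0.109, 0.0424, 0.0424 and 0.096, so the cell cycle, oxidative phosphorylation, DNA repair and cholesterol calls were lost. The p53 target (14 of 23 genes 2-fold or more higher in Ramos), apoptosis (21 of 26) and glycolysis (18 of 19) lists had adjusted p = 0.041, 0.043 and 0.043, and adjusted p = 0.096, 0.096 and 0.541 with an estimated correlation. The p53 target and glycolysis medians of -1.91 and -2.16 were no further toward Ramos than those of 1000 random lists of genes with like mean values, -1.92 and -2.59. Of the 26 called lists here, 9 had a median between the 2.5th and 97.5th percentiles of such lists, these 2 and the basal, colon epithelial, T and NK cell, HOX, receptor tyrosine kinase, cholesterol and housekeeping lists. After quantile normalization 17 B cell, 12 germinal centre, 13 pan-leukocyte, 7 class I, 22 cell cycle, 25 ribosomal protein, 25 oxidative phosphorylation and 21 DNA repair genes were 2-fold or more higher in Ramos. So were 15 MYC target, 12 housekeeping, 12 cholesterol synthesis, 12 p53 target, 13 apoptosis and 5 glycolysis genes. The medians of these 10 growth and housekeeping lists remained toward Ramos after quantile normalization.

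Over all genes, 18001 differed between CCD18 and Ramos by limma, 7647 higher in CCD18 and 10354 in Ramos, and arrays did not overlap for 98.6% of genes. By 2-fold or more 1112 genes were higher in CCD18 and 7766 in Ramos as deposited, 6803 and 5018 after quantile normalization, 7357 and 5982 after centring on array medians, and 14085 and 1183 after centring on the housekeeping list. The largest differences toward CCD18 were those of C2 at 41.4-fold, whose second probe set differed by 0.17 on the log2 scale only, VIM, the gephyrin gene GPHN at 24.2-fold, the Ras pathway inhibitor SPRED1 at 19.1-fold, the nuclear receptor NR4A2 at 17.3-fold, NFIB at 17.1-fold and SNX4 at 16.4-fold. Toward Ramos they were MPLKIP at 630-fold, RPS13 at 424-fold, the spliceosomal RNA gene RNU5E-1 at 383-fold, MSMO1, the adaptor SH3KBP1 at 348-fold, RPS3 at 346-fold, RPL14 at 322-fold and the nuclear long noncoding RNA MALAT1 at 292-fold. All 8 lay below the olfactory receptor median in CCD18, and against it MPLKIP was 232-fold, RPS13 316-fold and MSMO1 111-fold higher. Of 55 genes examined singly in this comparison, not all of which are named here, 23 lay at or below the olfactory receptor median of the lower line. C2 and SNX4 were among them, and against that median SNX4 was 4.76-fold higher in CCD18. Other probe sets of MPLKIP, SH3KBP1, RPL14 and MALAT1 differed less, by as little as -1.59, -2.21, -1.08 and -5.93 on the log2 scale, where the ones used differed by -9.30, -8.44, -8.33 and -8.19. All 55 genes examined singly in this comparison passed, with a median SE of 0.012, a largest SE of 0.74 (C2) and 10 genes with no spread in either line. Of 687 list memberships, 679 passed both with p adjusted over all genes and with p adjusted over the list alone. Of the 26 list calls here, 13 were lost with an estimated correlation. After quantile normalization the basal, integrin, p53 target and glycolysis calls were lost, at camera adjusted p = 0.063, 0.061, 0.12 and 0.2. The plasma cell list gained one toward Ramos, at adjusted p = 0.044 against 0.1 as deposited, and at adjusted p = 0.36 with an estimated correlation as well.

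The genes that set each line apart were those 2-fold or more higher than in both other lines. They numbered 3388 in MCF7, 177 in CCD18 and 1281 in Ramos, but 1150, 5349 and 1237 after quantile normalization over the 9 arrays, 1246, 5644 and 1844 after centring on array medians, and 199, 13207 and 549 after centring on the housekeeping list. In MCF7 the smaller of the 2 folds as measured was largest for DKK1 at 352-fold, MAL2 at 273-fold, the calcium binding protein NECAB1 at 244-fold, NPY1R at 214-fold, CDH1 at 192-fold, the amino acid transporter SLC7A2 at 183-fold, SPTSSB at 181-fold and NRIP1 at 169-fold. In CCD18 it was largest for VIM at 23.7-fold, C2 at 14.1-fold, PRRX1 at 9.63-fold, FGF10 at 8.25-fold, TWIST2 at 7.11-fold, the cofactor ZFPM2 at 6.76-fold, the calponin CNN3 at 6.21-fold and the Rho GTPase RHOJ at 6.02-fold. In Ramos it was largest for IFI16 at 277-fold, JCHAIN at 274-fold, LDHB at 249-fold, RASGRP3 at 209-fold, the lymphocyte receptor SLAMF6 at 205-fold, ST6GAL1 at 203-fold, EVI2B at 150-fold and MS4A1 at 149-fold. The order within MCF7 and Ramos is uncertain, since many of these genes lay at or below the olfactory receptor median in another line. With such values raised to that median, the smaller fold was 183 for DKK1, 217 for MAL2, 150 for NECAB1, 70.6 for NPY1R and 105 for NRIP1, against 192 for CDH1. In Ramos it was then 105 for IFI16, 150 for LDHB, 93 for RASGRP3, 132 for SLAMF6, 107 for EVI2B and 123 for MS4A1, against 274 for JCHAIN and 203 for ST6GAL1. In CCD18 only CNN3 moved, to 5.17. Each of these 24 genes kept its direction after quantile normalization. By a moderated F test in limma, 18282 of 18381 genes differed among the 3 lines.

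Each list was tested for an excess of such genes with a one-sided Fisher's exact test, adjusted over 96 tests. The test takes genes as independent, which genes that vary together are not, so its p-values can overstate the strength of a call. The MCF7 genes held 25 of the 27 epithelial genes, where 5.0 were expected (exact test, adjusted p = 4.6e-15), and 18 of the 19 luminal genes, where 3.5 were expected (1.8e-11). They also held 16 of 28 receptor tyrosine kinases against 5.2 expected (5.8e-05), a call that was lost after quantile normalization, at 4 against 1.8 expected and an exact adjusted p = 0.43. The CCD18 genes held 5 of the 26 fibroblast and mesenchymal genes, namely CDH2, PRRX1, TWIST1, TWIST2 and VIM, where 0.25 were expected (5.2e-05), and no other list was called for CCD18. After quantile normalization the fibroblast count was 15 against 7.6 expected (adjusted p = 0.019), and the collagen, HOX and T and NK cell lists were called as well, at 1.7e-05, 0.00013 and 0.02. The Ramos genes held 20 of 22 B cell identity genes against 1.5 expected (1.2e-19), 14 of 18 germinal centre genes against 1.3 (4.5e-12), and 14 of 19 pan-leukocyte genes against 1.3 (1.2e-11). They also held all 10 MHC class I genes against 0.70 (4.2e-11), 9 of 11 MHC class II genes against 0.77 (2.5e-08) and 6 of 11 plasma cell genes against 0.77 (0.00034). Also among them were 10 of 27 interferon response genes against 1.9 expected (Fisher's exact test, adjusted p = 7.1e-05), a call lost after quantile normalization at adjusted p = 0.059. Of the 11 calls, 9 held after quantile normalization. When centred on the housekeeping list, 5 calls were lost and 2 gained.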

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

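The tests of one median and one median absolute deviation, of a floor on the spread, of a fit without the 3 CCD18 arrays, of an estimated correlation after quantile normalization and of lists among the genes that set a line apart were chosen only after the results were seen. Genes 2-fold or more apart numbered 13339 for CCD18 versus Ramos with arrays centred on their medians, and 15346 for MCF7 versus CCD18 and 15268 for CCD18 versus Ramos when centred on the housekeeping list. Genes higher than in both other lines numbered 1246 in MCF7 and 5644 in CCD18 when centred on medians, 1150 and 5349 after quantile normalization, 1023 and 4972 at one median and median absolute deviation. When centred on the housekeeping list they numbered 199, 13207 and 549 in MCF7, CCD18 and Ramos. These shifts follow from the construction, since each scaling resets the level of every array: the median MCF7 minus CCD18 difference of 1.08 became -0.41, -0.46, -0.26 and -3.27. Of 212 differences of genes examined singly, not all of which are named here, TCF4 for CCD18 versus Ramos reversed. It stood at 0.09 (quantile), 0.96 (housekeeping) and 0.49 (one median and median absolute deviation). FN1, NT5E and COL12A1 for MCF7 versus CCD18 reversed at -1.83, -2.09 and -2.42 (housekeeping), and LOXL2 for CCD18 versus Ramos at 0.48 (housekeeping). The other 4443 values of the 212 differences under the alternatives kept their direction and stayed past the threshold. With all 28176 probe sets, 27651 differed among the lines, since more were tested. Higher than in both other lines were 4285 in MCF7, 387 in CCD18 and 1621 in Ramos. From 177 genes, the CCD18 count rose by a larger share than the number tested did. The cause of this rise was not tested. Limma treat called 11630, 8261 and 11974 for MCF7 versus CCD18, MCF7 versus Ramos and CCD18 versus Ramos, since it asks for more than a 1.5-fold difference. The count of 56 list calls became 32 when centred on the housekeeping list, 28 with an estimated correlation and 0 with that after quantile normalization, where the cause was not tested. It was 11 without the 3 CCD18 arrays, where only 32 tests remain, and 96 with fry, which does not compare a list with other genes. List results that reversed were the apoptosis list for MCF7 versus CCD18 when centred on the housekeeping list (adjusted p = 0.964), where the cause was not tested, and 4 with fry. The latter were the colon epithelial (8.84e-26) and HOX lists (1.12e-19) for MCF7 versus CCD18, the apoptosis list for MCF7 versus Ramos (1.04e-23) and the integrins for CCD18 versus Ramos (4.83e-24), where the cause was not tested. Of all list results under the alternatives, 1799 stayed on their side of the threshold, 174 lost and 70 gained a call. A turn of direction was counted only for lists called as deposited, so the 1799 include uncalled lists that turned. For lists among the genes that set a line apart, 1897 results stayed on their side of the threshold, 9 lost and 14 gained a call.

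Leaving out each array in turn gave 17802 to 17887 genes for MCF7 versus CCD18 (9708 to 9719 by 2-fold or more), 17461 to 17673 for MCF7 versus Ramos (5351 to 5375), 17961 to 18010 for CCD18 versus Ramos (8869 to 8891). It gave 18250 to 18270 among the 3 lines, 3378 to 3412, 174 to 179 and 1273 to 1286 higher in MCF7, CCD18 and Ramos than in both other lines, and 53 to 57 list calls. With the replicate number as a block the counts were 17831, 17527 and 17972, and 56 lists were called. Only 3 of 9 arrays correlated best with an array of their own number in another line. Replicate values were often identical and distributions were matched within each line, so this does not settle whether the numbers pair arrays. The low and narrow range of the CCD18 signal limits which differences can be seen there.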

Other observations

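The tests of the low CCD18 signal, of the identical replicate values and of the neighbour runs seen only with all genes were chosen only after the results were seen. Members of several gene lists differed between MCF7 and Ramos without a call for the whole list. Of all genes, 21.7% were 2-fold or more higher in MCF7 and 7.41% in Ramos as deposited. After quantile normalization these shares were 11.6% and 9.84%. Small list-wide differences here depend on the scaling, and for 18 of the 32 lists the median difference took both signs over the deposited values and 4 rescalings. Of 28 receptor tyrosine kinases 16 were 2-fold or more higher in MCF7 and 2 in Ramos (camera adjusted p = 0.15). The hepatocyte growth factor receptor MET was 29.6-fold and ERBB3 22.4-fold higher in MCF7, and after quantile normalization camera called the list at adjusted p = 0.0087, a call lost at adjusted p = 0.41 with an estimated correlation. The T and NK cell list likewise gained a call toward Ramos, at adjusted p = 0.016 against 0.3 as deposited, and adjusted p = 0.36 with an estimated correlation as well. Integrins went both ways: 10 of 23 were 2-fold or more higher in MCF7 and 3 in Ramos (adjusted p = 0.55). Toward MCF7 went the hemidesmosome subunit ITGB4 at 35.9-fold and the collagen receptor subunit ITGA2 at 30.5-fold, and toward Ramos the leukocyte integrins ITGAL at 23.0-fold and ITGA4 at 16.1-fold. Matrix remodelling genes were 2-fold or more higher in MCF7 for 12 of 26 and in Ramos for 1 (adjusted p = 0.14), with PLOD2 at 277-fold, TIMP1 at 33.3-fold and the collagen chaperone SERPINH1 at 16.2-fold. Fibroblast and mesenchymal genes were 2-fold or more higher in each line for 3 of 26 (adjusted p = 0.73). Examples were FN1 at 13.0-fold and SNAI2 at 8.71-fold toward MCF7, and TCF4 at 101-fold and ZEB1 at 15.7-fold toward Ramos. In the TGF-beta pathway list 9 of 24 genes were 2-fold or more higher in MCF7, such as BMP4 at 17.9-fold and TGFB2 at 16.6-fold, and 3 in Ramos (adjusted p = 0.34), or 7 and 4 after quantile normalization.

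Among growth and stress genes, 9 of 30 DNA repair genes were 2-fold or more higher in MCF7, such as BRIP1 at 8.19-fold and RAD51C at 5.91-fold, and 1, the damage kinase ATM at 9.68-fold, in Ramos (camera adjusted p = 0.97). Cell cycle genes were 2-fold or more higher in MCF7 for 8 of 32, such as AURKA at 3.53-fold, and in Ramos for 1, E2F2 at 2.88-fold (adjusted p = 0.73). The p53 targets GDF15 and CDKN1A were 12.6-fold and 4.46-fold higher in MCF7, and 6 of 23 genes of that list were 2-fold or more higher in MCF7 and 3 in Ramos (adjusted p = 0.49). The MYC gene itself, which Burkitt's lymphoma translocates to an immunoglobulin locus, was 2.56-fold higher in Ramos, and of 23 MYC target genes 5 were 2-fold or more higher in MCF7 and 2 in Ramos as deposited (adjusted p = 0.82), or 0 and 3 after quantile normalization. Of 27 HOX genes 6 were 2-fold or more higher in MCF7 and 0 in Ramos as deposited, such as HOXC13 at 10.7-fold and HOXC9 at 7.2-fold toward MCF7 (adjusted p = 0.31), or 2 and 1 after quantile normalization. Cholesterol synthesis (5 of 17 in MCF7, 2 in Ramos, DHCR7 at 4.05-fold higher in MCF7) and oxidative phosphorylation (4 of 33 in MCF7, none in Ramos, COX6C at 4.53-fold) had adjusted p = 0.97 and 0.62. After quantile normalization the counts toward MCF7 and Ramos were 4 and 1 for DNA repair, 3 and 1 for cell cycle, 6 and 3 for p53 target, 3 and 3 for cholesterol synthesis and 1 and 0 for oxidative phosphorylation genes. As deposited, the MYC target, HOX, cell cycle and p53 target shares toward MCF7 lay near the 21.7% of all genes. The oxidative phosphorylation share lay below it. These counts therefore do not set those lists apart from genes at large.

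The protein-coding signal was lower on the CCD18 arrays. Separate normalization of each line, as a difference in distribution alone, is argued against as the whole cause. After quantile normalization over the 9 arrays the housekeeping list was still 1.49 (95% bootstrap interval 0.92 to 2.39) lower in CCD18 than in MCF7. It was 1.04 (0.41 to 1.73) lower than in Ramos, against 0.31 between MCF7 and Ramos. The intervals run over 24 genes, which are not independent replicates, and the 0.31 was given none. Rescaling finished values cannot undo a background correction or median polish run for each line, so an effect of those steps stays open. Less labelled target from messenger RNA on the CCD18 arrays stays open. Of 171 genes at a log2 value of 12 or more in MCF7 and Ramos, 93.0% lay 2-fold or more lower in CCD18, but these genes were chosen as bright in the other lines, so this share does not decide it. A biological difference of the fibroblast line stays open as well, because all CCD18 arrays share one line and one normalization. The difference from MCF7 had an SD of 2.02 over the ribosomal protein genes, against 0.564 between MCF7 and Ramos, but an uneven loss does not decide between the explanations. Biology cannot be told apart from the labelling, because no measure of RNA quality and no spiked standard was used here.

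Replicate arrays of a line often held identical values. One array deposited 3 times is argued against, because at least 27.8% of the genes of each line had values that differed between its arrays. Median polish within a line, the summary step of RMA, could give the identical values: in a simulation of 3 arrays with independent noise, 65.9% of probe sets of 24 probes received 3 identical summaries, and 1.45%, 24.4% and 81.0% of those of 6, 12 and 27 probes did. The number of probes per probe set was not used here, and whether the arrays came from separate cultures stays open.

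Neighbouring genes differed together between MCF7 and Ramos, measured as means over windows of 15 protein-coding genes of the log2 difference less its median, with single genes limited to 3. Chance order of the genes is argued against, since 99 of 16562 windows lay beyond the 95th percentile of the largest or smallest window of 1000 shuffled orders. With all genes the thresholds were 1.46 and -1.21. Shuffles of the 9254 genes above the array median in both lines gave lower ones, 1.17 and -1.01. Among these genes 169 of 8932 windows passed. This argues against genes used by one cell type only as the whole cause. Gene families are not removed by that filter, so families used by both lines stay open. A run on chromosome 19 (19645198 to 23147221) had a peak window of zinc finger genes only, ZNF14 to ZNF493. Of the 12 runs found with all genes, 8 were seen only there. For these 8 runs gene families, such as protocadherins on chromosome 5 (140801057 to 141641064) and HLA genes on chromosome 6 (32128707 to 33278825), stay open. The run on chromosome 17 (58489537 to 63446639, GRCh38.p14, MTMR4 to CYB561) held 36 genes, of which 33 lay above the median difference toward MCF7 and 23 by 2-fold or more, such as RPS6KB1 at 10.6-fold, TBX2 at 9.61-fold and PPM1D at 8.27-fold as deposited. A DNA copy number difference between the lines is a candidate explanation, with a highest window mean of 2.15 among the genes above the median, in the same region of chromosome 17, and it stays open because no DNA was measured.

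Other splits of the same arrays mix the 3 lines, so line differences enter their groups and widen the spread within them, and the counts below only set the grouping by line against mixed groups. The number of genes that differed among the 3 lines was 18282, against 11193 in the highest other split. Only 1 of 100 splits, the real one, gave as many. Likewise only the real split gave as many genes higher than in both other lines in MCF7 (3388 against 2556), CCD18 (177 against 0) and Ramos (1281 against 897). Since the mixed groups hold line differences as spread, their lower gene counts were built in. These gene counts therefore do not test chance differences between cultures. For the number of list calls, 70 of 100 splits gave 56 or more, the highest other 82, so this count does not exclude chance and says nothing on any single list. For the pairwise counts, 10 splits are too few for a share under 0.05. The real values were 17871, 17622 and 18001 genes, and 9710, 5358 and 8878 by 2-fold or more, for MCF7 versus CCD18, MCF7 versus Ramos and CCD18 versus Ramos. The highest other split of each gave 0.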
